A study of Rattus norvegicus with 12 samples.

How the data were processed

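The series holds 12 Affymetrix arrays of total RNA from L4/L5 dorsal root ganglia of adult male Sprague Dawley rats, 3 for each of 4 groups (HP sham, HP SNL, LP sham and LP SNL). Group and replicate number were taken from the sample titles. Per the labels' protocols, RNA was isolated with a Qiagen RNeasy kit, labelled with biotin and hybridised by the Affymetrix manual. The deposited table holds 1 intensity per probe set and array on a linear scale, from 0 to 13930.7, for 15923 probe sets. Per the submitters' processing notes the only tool named is RMA, with no version. The values do not look like RMA output alone: every array has a mean of 500.1 after leaving out the lowest and highest 2% of values, the pattern of Affymetrix global scaling, so which steps the authors ran is not settled here. The image software and further steps are not given in the sources used here.

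The plan had assumed log2 values, with log2 of the value plus a pseudocount of 1 as the fallback if linear values under 1 occurred. Of 191076 values 109 were below 1 and 3 were 0, so log2(value + 1) was used, with no further normalization. Probe sets were named by the platform annotation, with symbols updated through a RefSeq gene table of the rat assembly GRCr8, by gene identifier for 12748 and by accession for 2, while 33 kept the platform's symbol. In all, 12783 probe sets had 1 symbol, 312 had several and 2771 had none apart from the 57 controls. A probe set with several symbols was not used for a named gene. Of 10411 genes, 1868 had more than 1 probe set, and the probe set with the highest mean over all arrays stood for the gene. Where a gene had several probe sets, all passed for 69 of the 375 genes with any past in HP and for 85 of 414 in LP. Precision depends on brightness: the median replicate SD was 0.613 log2 units in the dimmest 25% of probe sets and 0.135 in the brightest. The number of arrays limits the precision.

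All 12 arrays entered 1 limma fit of 4 group means (limma 3.58.1 with statmod 1.5.0 in R 4.3.3; lmFit, contrasts.fit and eBayes, 8 residual degrees of freedom, 2.05 prior degrees of freedom). The contrasts were SNL against sham in HP, in LP and averaged over the lines, LP against HP after sham and after SNL, and the interaction. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes of a contrast and a threshold of 0.05. The 31 gene lists, fixed before the data were examined, were tested with camera at a preset correlation of 0.01 and adjusted over the lists of a contrast, with camera at an estimated correlation and fry beside it. Adjustment over the list alone was computed too. The lists covered nerve injury and regeneration, nociceptor markers, potassium channels, sodium and calcium channels, neurotransmitter receptors, the cytoskeleton, synaptic vesicles, T and NK cells, macrophages, neutrophils, mast cells, protease inhibitors, antigen presentation, complement, cytokines, the interferon response, satellite glia, myelin, Schwann cell repair, cholesterol biosynthesis, extracellular matrix, cell cycle, immediate early genes, the respiratory chain, ribosomal proteins, muscle, red blood cells, adipocytes, endothelium, fibroblasts and central nervous system glia.

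Named genes followed a rule set before the data were examined: Serpina3n and Elane in each contrast, the 10 largest increases and 10 largest decreases among genes past the threshold in each ligation and line contrast (all if fewer), the 10 smallest p-values of the interaction if fewer than 5 passed, and up to 4 members with the smallest p of each list. Acta1, for which only signals are given, was added after its values were seen. The fit was tested on simulated data drawn from the measured means and spreads, with known fold changes. For SNL against sham in HP it recovered 35.8%, 59.7% and 90.9% of genes changed 1.5-fold, 2-fold and 4-fold. For LP against HP after SNL it recovered 32.8%, 65.7% and 92.4%, and for the interaction 6.0%, 32.8% and 81.8%. Each share was over 66 or 67 changed genes, among 10411 simulated genes drawn independently of each other. Far fewer genes were changed than limma called after ligation in the measured data, so recovery there may differ.

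Alternatives fixed before the data were examined were the replicate number as a block, leaving out the dimmest 25% of genes, quantile normalization, median centring, trended and robust variance, array weights, a fit of only the arrays compared, every probe set as its own test, the mean of a gene's probe sets, leaving out each array in turn, and the other set tests. Pseudocounts of 16 and 32, the log2 beta-actin 3' to 5' probe set ratio as a covariate, and the nociceptor list without Scn10a and Scn11a were chosen after seeing the data. Probe sets without a single gene name were left out of the named results and tested apart.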

Results

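Gene expression was measured in dorsal root ganglia, the clusters of sensory neuron cell bodies beside the spinal cord, from adult male Sprague Dawley rats of the High Pain (HP) and Low Pain (LP) genetic sub-lines. In one arm the L4 and L5 spinal nerves were tied (spinal nerve ligation, SNL, a rat model of neuropathic pain) and the ganglia at L4/L5 were taken 3 days later, and in the other arm the animals had a sham operation that spared the nerve. The 12 Affymetrix arrays form 4 groups of 3: HP sham, HP SNL, LP sham and LP SNL. The median probe set signal per array lay between 278.4 and 313.2. Correlations of log2 signals between arrays of the same group lay between 0.941 and 0.965, and those between arrays of different groups between 0.923 and 0.961. Nothing in the labels says that replicates are separate animals, so p-values measure only the spread between these samples, which may be technical. The number of arrays, 3 per group, limits the precision. Signals are group means ± SD with n = 3, and log2 differences are given ± SE, both on the scale of log2 of the signal plus 1, which understates the change of dim genes.

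The first question was what ligation did in HP rats. Among the strongest increases, the cell cycle genes Cdkn3, which encodes a phosphatase of cyclin-dependent kinases, and Kif20a, a kinesin of dividing cells, rose by log2 3.53 ± 0.55 and 2.87 ± 0.45. The chemokines Ccl6 and Cxcl14 rose by 3.33 ± 0.46 and 3.20 ± 0.39, Cxcl14 from a signal of 519 ± 365 to 4098 ± 614. Apobec1, an RNA editing enzyme, Cldn4, a tight junction protein, Sox11, a transcription factor of developing and regenerating neurons, and Gch1, the first enzyme of tetrahydrobiopterin synthesis, rose by between 2.73 ± 0.48 and 3.22 ± 0.54. The other probe set of Gch1 had a log2 difference of 0.55. Among the strongest decreases, the synaptic scaffold gene Caskin1 fell by 4.16 ± 0.21 on the log2 scale, from 292 ± 42.0 to 15.6 ± 3.97. Its signal after SNL lay near the 5th percentile of the HP SNL arrays (15.8, 13.7 and 14.3), so the size of this fall is uncertain. The phospholipase C gene Plcd4 fell by 4.05 ± 0.42, the serotonin receptor gene Htr1d fell by 3.66 ± 0.16 and the cell adhesion gene Cntn4 fell by 3.45 ± 0.25. Kcns1, a modulatory potassium channel subunit of sensory neurons, fell by 3.09 ± 0.32, Acp3, an acid phosphatase of nociceptors, fell by 2.68 ± 0.25, and the secretory granule gene Chga fell by 2.54 ± 0.53. By limma, 1419 of 10411 genes passed an adjusted p of 0.05, 731 higher and 688 lower, and 161 and 157 of these had changed at least 2-fold. The count was 816 with each array's actin 3' to 5' ratio as a covariate, and 846, 866, 945 and 875 without HP sham replicate 1, HP sham replicate 3, HP SNL replicate 2 and HP SNL replicate 3. In HP the actin ratio did not overlap between sham (1.483 to 1.847) and SNL (1.118 to 1.342). The actin covariate can thus take up part of the ligation effect itself in HP. Sox11 and Chga lost the call only with that covariate, at log2 differences of 2.04 against 2.81 without it and -2.63 against -2.54 (adjusted p = 0.0939 and 0.0518, the highest over the alternatives, where the lowest were 0.00204 and 0.00131).

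Another 5 genes among the largest changes in HP passed narrowly and lost the call in some alternatives, most often with the log2 difference near its full value. Fcgr2b, an inhibitory Fc receptor, had a log2 difference of 2.96 (adjusted p over alternatives 0.00245 to 0.156), and lost the call without HP sham replicate 3 (0.0854), HP SNL replicate 2 (0.0726) and HP SNL replicate 3 (0.0736), at differences of 2.37 to 2.87. With the actin covariate the difference of Fcgr2b was 1.71 (0.156). Serpinb2, a protease inhibitor of macrophages, had 2.94 (0.00315 to 0.149). Its adjusted p was 0.0523 and 0.0758 without HP sham replicates 2 and 3, and 0.0617, 0.0652 and 0.0588 without HP SNL replicates 1, 2 and 3, at differences of 2.29 to 3.06. With the actin covariate the difference of Serpinb2 was 1.75 (0.149). Myh4, a fast muscle myosin, had -3.64 (0.0129 to 0.117). Without HP sham replicates 1 and 3 it had 0.108 and 0.117, without HP SNL replicates 1, 2 and 3 it had 0.101, 0.07 and 0.0864, and without LP sham replicate 2 it had 0.0515, at differences of -3.89 to -3.26. Bckdha, a subunit of the branched-chain keto acid dehydrogenase, had -2.99 (0.00469 to 0.124). The values were 0.0997, 0.0918 and 0.089 without HP sham replicates 1, 2 and 3, 0.0626, 0.124 and 0.0701 without HP SNL replicates 1, 2 and 3, and 0.0515 without LP sham replicate 2, at differences of -3.23 to -2.51. Sh3gl2, an endophilin of synaptic vesicle recycling, had -2.66 (0.00238 to 0.149). It had 0.098, 0.104 and 0.104 without HP sham replicates 1, 2 and 3, 0.0537 and 0.1 without HP SNL replicates 2 and 3, 0.0529, 0.0595 and 0.0567 without LP sham replicates 1, 2 and 3, and 0.0598, 0.0577 and 0.06 without LP SNL replicates 1, 2 and 3. The difference of Sh3gl2 was -1.64 without HP SNL replicate 2 and -2.71 to -2.60 in the other cases. It also lost the call with the actin covariate (-2.77, 0.123), in a fit of the HP arrays alone (0.149) and with every probe set as its own test (0.0506).

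Genes of the injured neuron moved in both directions in HP. Of 36 measured nerve injury and regeneration genes, 28 rose and 1 fell (32 and 1 adjusted over the list alone), with a median log2 difference of 1.22 and a camera adjusted p of 2.22e-22. They included Sprr1a, a growth-associated protein (2.29 ± 0.15), the transcription factor gene Jun (1.63 ± 0.11), the GDNF co-receptor gene Gfra1 (1.35 ± 0.10) and the secreted lectin gene Reg3b (2.15 ± 0.16). Of 26 nociceptor and sensory neuron markers, 16 fell (18 adjusted over the list alone; median -0.64; camera adjusted p = 3.07e-11). The sodium channel genes Scn10a and Scn11a, both typical of nociceptors, fell by 1.30 ± 0.08 and 1.74 ± 0.21, the acid-sensing channel gene Asic1 fell by 1.25 ± 0.11 and the capsaicin receptor gene Trpv1 fell by 1.43 ± 0.17. Of 33 voltage-gated potassium channel genes, 12 fell and 1 rose (17 and 1 adjusted over the list alone; camera adjusted p = 4.84e-06), with Kcns3 down by -1.63 ± 0.11 and Kcnv1 by -1.37 ± 0.20. Of 30 synaptic vesicle and exocytosis genes, 8 fell and 1 rose (13 and 1 adjusted over the list alone; camera adjusted p = 0.000176), with Rab3a at -1.05 ± 0.09, Scg2 at -1.45 ± 0.16 and the riser Syt4 at 0.63 ± 0.09. Of 30 sodium and calcium channel subunits, 8 fell and 4 rose (8 and 5 adjusted over the list alone), among them Scn1a (-1.39 ± 0.15) and Cacna2d1, the subunit bound by gabapentin (1.14 ± 0.12). The camera adjusted p of this list was 0.0259, but adjusted p = 0.0752 with an estimated correlation, 0.0618 with the actin ratio as a covariate and 0.0534 without HP sham replicate 3, in a range of 0.00864 to 0.0752 over the camera alternatives. With fry, which tests a list against no change and not against other genes, it was 0.000377. Among 34 GABA, opioid and glutamate receptor genes, 5 fell and 1 rose, the same counts as adjusted over the list alone (camera adjusted p = 0.32), and Gabbr2, a GABA-B receptor subunit, fell by 1.15 ± 0.11. The neurofilament and neuronal cytoskeleton list held 4 risers and 3 fallers of 25, again the counts adjusted over the list alone (camera adjusted p = 0.957, median -0.03 but mean 0.09), with Stmn4, a stathmin of growing axons, at 1.83 ± 0.23.

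Macrophage markers rose in HP, with some but not all other lists of immune and stromal genes. Of 32 macrophage and monocyte markers, 22 rose (23 adjusted over the list alone), with a median of 1.01 and a camera adjusted p of 7.26e-18. The complement C1q genes C1qb and C1qc rose by 2.02 ± 0.17 and 1.46 ± 0.13, and the Fc receptor gamma chain gene Fcer1g by 1.30 ± 0.14. Of 33 cell cycle genes, 11 rose (18 adjusted over the list alone, with 1 lower; camera adjusted p = 2.24e-08), and of 27 endothelial and mural cell markers 11 rose (12 adjusted over the list alone; camera adjusted p = 3.82e-06), with Tie1, an endothelial receptor, at 0.71 ± 0.11. Among 35 serpins and other protease inhibitors, 8 rose and 2 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.00109), with A2m at 2.49 ± 0.22 and Timp1 at 1.73 ± 0.16. Of 24 cholesterol biosynthesis genes, 5 fell (6 adjusted over the list alone; camera adjusted p = 0.000897), including squalene epoxidase, Sqle (-0.68 ± 0.11). Extracellular matrix genes and their proteases had 20 risers and 1 faller of 47 (25 and 1 adjusted over the list alone; camera adjusted p = 3.65e-11, but adjusted p = 0.0524 with an estimated correlation), with the metalloprotease Mmp16 at 1.35 ± 0.12. Antigen presentation genes of MHC classes I and II had 7 risers of 28 (10 adjusted over the list alone; camera adjusted p = 0.00021, but adjusted p = 0.0819 with an estimated correlation), and RT1-DMb rose by 0.85 ± 0.09. Complement had 8 risers and 1 faller of 24 (9 and 1 adjusted over the list alone; camera adjusted p = 0.00144, but adjusted p = 0.0524 with an estimated correlation). Its faller was Cd55, an inhibitor of complement (-1.24 ± 0.14). Cytokines, chemokines and their receptors had 6 risers and 1 faller of 50 (7 and 2 adjusted over the list alone; camera adjusted p = 0.00629, but adjusted p = 0.143 with an estimated correlation). Interferon response genes had 7 risers of 28, also 7 adjusted over the list alone (camera adjusted p = 0.00583, but adjusted p = 0.138 with an estimated correlation), with Gbp2 at 1.74 ± 0.24.

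Further lists in HP covered glia, fibroblasts, muscle, other immune cells and immediate early genes. Gfap, the intermediate filament of activated glia, rose by 1.67 ± 0.09, and Cadm1, an adhesion molecule, fell by 0.93 ± 0.10. These belong to the satellite glia markers, of which 5 rose and 1 fell of 15 (7 and 2 adjusted over the list alone; camera adjusted p = 0.0136, but adjusted p = 0.0585 with an estimated correlation and 0.111 with the mean of a gene's probe sets; camera range 0.00778 to 0.111; fry 9.95e-05). Schwann cell repair genes had 6 risers and 2 fallers of 22 (7 and 2 adjusted over the list alone; camera adjusted p = 0.0035, but adjusted p = 0.0585 with an estimated correlation). Immediate early and heat shock genes had 9 risers and 2 fallers of 39, the counts adjusted over the list alone too (camera adjusted p = 0.00675, but adjusted p = 0.166 with an estimated correlation and 0.0502 with the actin covariate; range 0.00185 to 0.166), with Atf3, a transcription factor induced by axon injury, at 2.50 ± 0.22. Fibroblast and meningeal markers had 6 risers of 27 (8 adjusted over the list alone; camera adjusted p = 0.00654, but adjusted p = 0.265 with an estimated correlation and 0.0722 with the actin covariate; range 0.00274 to 0.265). Myelin and Schwann cell genes held 1 riser and 3 fallers of 17, as adjusted over the list alone (camera adjusted p = 0.909, median 0.10 but mean -0.03). T cell and NK cell markers held 1 riser and 1 faller of 25 in both adjustments (camera adjusted p = 0.909, median 0.02 but mean and test below 0), the riser being Gzmb, a protease of cytotoxic cells, at 1.71 ± 0.28. Neutrophil markers and granule proteases held 1 riser of 16 in both adjustments (camera adjusted p = 0.0756, and 0.0303 and 0.0435 after quantile normalization and median centring; range 0.0219 to 0.365). The neutrophil list also passed in the fit of the HP arrays alone (0.0425) and without HP sham replicate 1 (0.0219), HP SNL replicate 1 (0.0309) and LP SNL replicate 3 (0.0447). Mast cell markers held 2 risers and 1 faller of 18 in both (camera adjusted p = 0.83; median 0.02 but mean -0.10). Skeletal muscle markers held 1 riser and 5 fallers of 32 in both (camera adjusted p = 0.0898, and 0.0205 with the mean of a gene's probe sets and 0.0109 and 0.0449 without HP sham replicate 2 and HP SNL replicate 2; range 0.0109 to 0.521). Acta1, skeletal muscle actin, had signals of 1232.7, 435.6 and 1015.7 in HP sham replicates 1, 2 and 3, and between 284.8 and 493.2 on the other 9 arrays. The actin 3' to 5' ratio, a sign of RNA integrity, averaged 1.70 in HP sham, 1.23 in HP SNL, 1.34 in LP sham and 1.12 in LP SNL. Its log2 was lower after SNL by -0.33 on average (exact permutation test within lines, two-sided, p = 0.05). In LP sham replicates 1, 2 and 3 the actin ratio was 1.877, 1.154 and 0.993. The GAPDH 3' to 5' ratio was 1.12, 1.17 and 1.095 in HP sham and 1.244, 1.066 and 1.211 in HP SNL. In LP it was 1.056, 1.095 and 1.092 after sham and 1.09, 1.183 and 1.084 after SNL, without such a fall. Whether RNA integrity differed with surgery is left open, and the GAPDH ratio was not used as a covariate.

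The next question was how LP rats responded to the same injury. In LP, Ccl6 and Cxcl14 rose by 4.36 ± 0.46 and 4.20 ± 0.39, and the proliferation genes Cks2, Mki67 and Kif20a by 3.96 ± 0.57, 3.93 ± 0.44 and 3.50 ± 0.45. Apobec1, the matrix gene Postn, the stromal marker Cd248, Cldn4 and the growth factor gene Tgfb1 rose by between 3.19 ± 0.41 and 3.80 ± 0.54. The other probe set of Cd248 had a log2 difference of 0. Htr1d fell by 3.69 ± 0.16, Acp3 fell by 3.64 ± 0.25, Caskin1 fell by 3.22 ± 0.21 and Plcd4 fell by 3.18 ± 0.42. Scn11a fell by 3.08 ± 0.21, from 2272 ± 656 to 261 ± 7.80, and Chga fell by 3.03 ± 0.53. The kinase gene Limk1, Ifitm10, the natriuretic peptide gene Nppb, a transmitter of itch neurons, and the kainate receptor gene Grik1 changed by between -2.90 ± 0.40 and -2.68 ± 0.45. By limma, 1504 genes passed, 797 higher and 707 lower, with 220 and 137 changed at least 2-fold. The count was 814 in a fit of the 6 LP arrays alone.

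Neuronal genes in LP moved as follows. Nociceptor and sensory neuron markers had 18 fallers of 26 (20 adjusted over the list alone; median -0.73; camera adjusted p = 4.91e-16), with Scn10a at -1.86 ± 0.08 and the substance P precursor gene Tac1 at -1.69 ± 0.15. Synaptic vesicle genes had 13 fallers and 1 riser of 30 (18 and 1 adjusted over the list alone; median -0.47; camera adjusted p = 4.98e-09), with Scg2 at -1.90 ± 0.16 and the vesicle glycoprotein gene Sv2b at -0.98 ± 0.10. Potassium channels had 13 fallers of 33 (13 adjusted over the list alone, with 2 higher; camera adjusted p = 5.3e-06), with Kcns3 at -2.04 ± 0.11 and Kcnd3 at -1.61 ± 0.16. Sodium and calcium channel subunits had 9 fallers and 4 risers of 30 (9 and 5 adjusted over the list alone; camera adjusted p = 0.0218, but adjusted p = 0.0762 with an estimated correlation). GABA, opioid and glutamate receptors had 7 fallers and 2 risers of 34 in both adjustments (camera adjusted p = 0.0542; camera range 0.0192 to 0.112; fry 0.00136), with Gabbr2 at -1.24 ± 0.11 and the metabotropic glutamate receptor gene Grm4 at -0.82 ± 0.10. By camera this list passed in 7 of 24 alternatives, among them quantile normalization (0.0211) and the fits without LP sham replicate 3 (0.0441) and LP SNL replicates 2 and 3 (0.0422 and 0.0358). The neurofilament and cytoskeleton list had 4 risers and 2 fallers of 25 (4 and 4 adjusted over the list alone; camera adjusted p = 0.216), with the tau gene Mapt at -0.96 ± 0.13 and Stmn4 at 1.51 ± 0.23. Nerve injury and regeneration genes had 27 risers and 1 faller of 36 (30 and 1 adjusted over the list alone; median 1.32; camera adjusted p = 5.1e-19), with Atf3 at 2.85 ± 0.22 and the stress gene Gadd45a at 2.34 ± 0.18.

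Among non-neuronal genes in LP, 22 of 32 macrophage and monocyte markers rose (26 adjusted over the list alone; camera adjusted p = 3.04e-17), with C1qb at 2.24 ± 0.17 and Gpnmb, a glycoprotein of phagocytes, at 2.49 ± 0.23. Cell cycle genes had 16 risers of 33 (20 adjusted over the list alone; camera adjusted p = 1.67e-09), extracellular matrix genes 26 risers and 1 faller of 47 (32 and 1 adjusted over the list alone; camera adjusted p = 5.24e-14), and endothelial and mural markers 10 risers of 27 (14 adjusted over the list alone; camera adjusted p = 1.33e-06), with the pericyte gene Rgs5 at 1.24 ± 0.19. Cholesterol biosynthesis genes had 7 fallers of 24 (10 adjusted over the list alone; camera adjusted p = 1.24e-05). Serpins and other protease inhibitors had 7 risers and 1 faller of 35 (9 and 1 adjusted over the list alone; camera adjusted p = 0.0231, but adjusted p = 0.0701 with an estimated correlation and 0.055 in the fit of LP arrays alone; camera range 0.000555 to 0.0701; fry 3.6e-05), with A2m at 2.76 ± 0.22. Antigen presentation genes had 4 risers of 28 in both adjustments (camera adjusted p = 0.000205, but adjusted p = 0.089 with an estimated correlation). Complement had 8 risers and 1 faller of 24 (9 and 2 adjusted over the list alone; camera adjusted p = 0.0101, but adjusted p = 0.09 with an estimated correlation), and Cd55 fell by 1.81 ± 0.14. Cytokines had 7 risers and 1 faller of 50 in both adjustments (camera adjusted p = 0.00263, but adjusted p = 0.112 with an estimated correlation), and interferon response genes 5 risers of 28 in both (camera adjusted p = 0.0208, but adjusted p = 0.191 with an estimated correlation). Schwann cell repair genes had 6 risers and 2 fallers of 22 in both (camera adjusted p = 0.00516, but adjusted p = 0.0762 with an estimated correlation), and Shh, a morphogen, rose by 3.12 ± 0.35. Immediate early genes had 11 risers and 4 fallers of 39 (14 and 4 adjusted over the list alone; camera adjusted p = 0.000243, but adjusted p = 0.0876 with an estimated correlation). Fibroblast markers had 7 risers of 27 (8 adjusted over the list alone; camera adjusted p = 0.00448, but adjusted p = 0.245 with an estimated correlation), with lumican, Lum, at 0.94 ± 0.15. Satellite glia markers had 5 risers and 1 faller of 15 (7 and 2 adjusted over the list alone; camera adjusted p = 0.277), with Gfap at 1.54 ± 0.09. Neutrophil markers had 2 risers of 16 in both adjustments (camera adjusted p = 0.068, and 0.0365 after median centring, 0.0495 with array weights and 0.0147 without LP SNL replicate 2; range 0.0147 to 0.338). T cell and NK markers had 1 riser, Gzmb, and 1 faller of 25 (1 riser adjusted over the list alone; camera adjusted p = 0.768). Mast cell markers had 1 riser of 18 in both (0.891, median -0.03 but mean 0.07), and myelin genes 1 riser and 1 faller of 17 in both (0.894, median 0.00 but mean and test below 0). Muscle markers had 1 riser of 32 over all genes (0.532), and by limma 0 adjusted over the list alone, with 4 at an unadjusted p under 0.05.

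**Figure D1:**
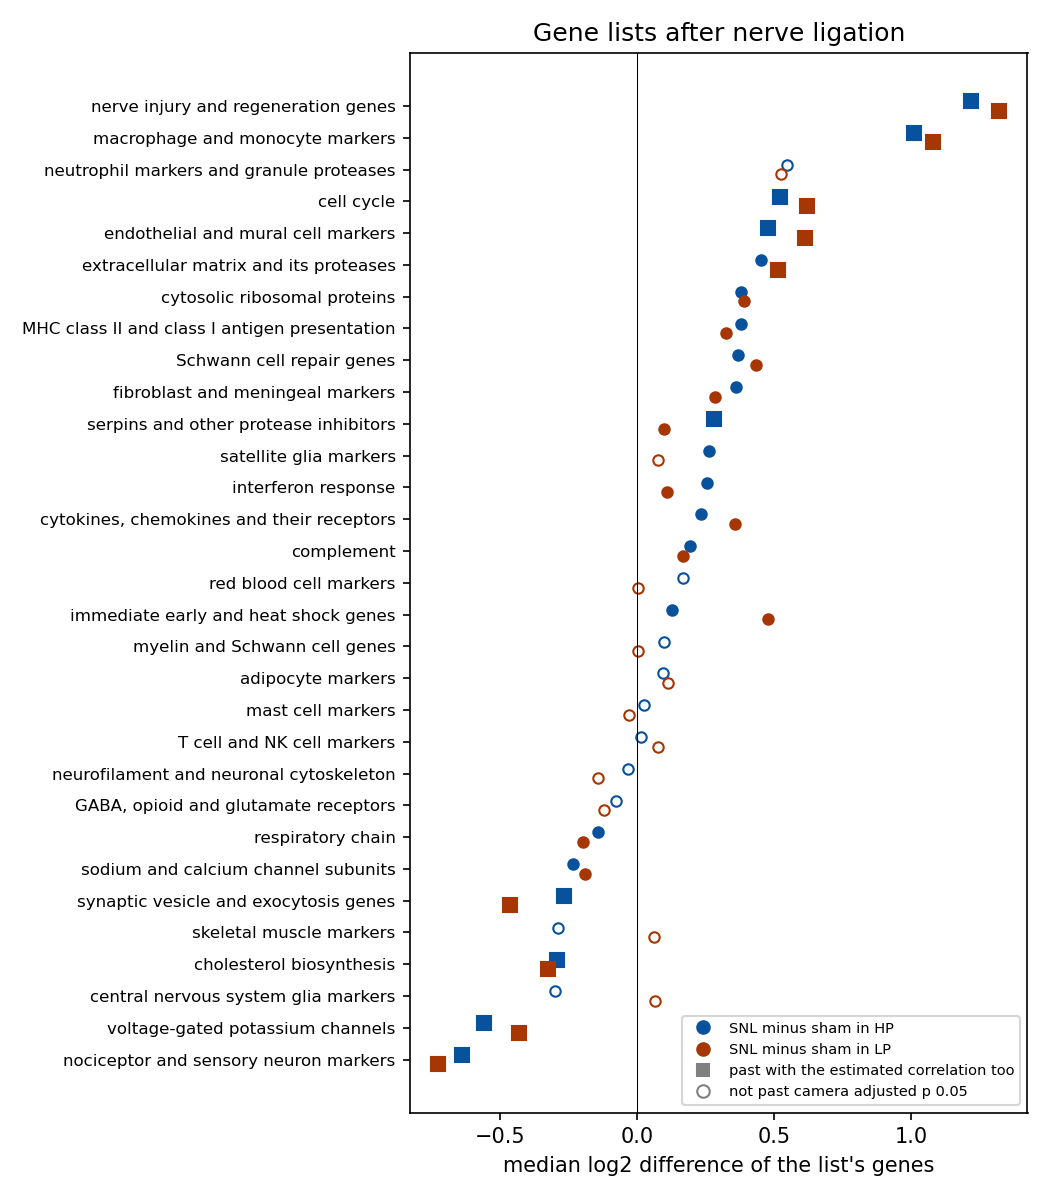
Median log2 difference between SNL and sham over the genes of each fixed list (x axis) in HP (blue) and LP (brown), where filled symbols passed camera at an adjusted p of 0.05, squares also with an estimated correlation, and open circles did not pass. Nociceptor markers lie lowest, at -0.64 in HP and -0.73 in LP, and nerve injury genes highest, at 1.22 and 1.32.

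With an estimated correlation, 9 of the 21 lists past in HP kept their call: the nerve injury, macrophage, cell cycle, endothelial and serpin lists, which rose, and the nociceptor, potassium channel, synaptic and cholesterol lists, which fell. In LP 9 of 20 kept it, the same lists with the extracellular matrix in place of the serpins. For serpins the LP response differed from the HP response by a median of 0.00 (camera adjusted p of the interaction 0.754), and for the extracellular matrix by a median of 0.04 and a mean of 0.18 (0.107). The extracellular matrix interaction passed in 7 of 23 camera alternatives (0.00149 to 0.887), among them the actin covariate (0.00149) and the fits without HP sham replicate 1 (0.0184), LP sham replicates 2 and 3 (0.0469 and 0.0159) and LP SNL replicate 2 (0.00377). Whether the lines differ in it is left open. These camera tests compare a list with all other genes, whereas fry tests only whether a list's genes move one way. After quantile normalization and median centring, each list call in the ligation comparisons that stood in these paragraphs kept its direction.

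Whether the lines responded alike was examined over all genes. Of the genes higher after SNL, 528 passed in both lines, where 56.0 would be shared by independent lists, and of those lower, 470 passed in both, where 46.7 would be shared. No gene was higher in HP and lower in LP, where independent lists would share 49.6 (limma, 0 genes; 4 at an unadjusted p under 0.05 in both lines). The opposite held for 1 gene, where independent lists would share 52.7. Across all 10411 genes the HP and LP log2 differences correlated with Pearson's r = 0.602 and Spearman's rho = 0.556, and across the 1924 genes past in either line with r = 0.866. These correlations are across genes, which are not independent replicates, and the lines share no arrays. The 1924 genes were picked by the differences that are correlated, which raises their r. Both contrasts use the same estimate of each gene's spread, so genes with a small spread pass more readily in both. The numbers for independent lists do not allow for this. Averaged over the lines, limma called 2583 genes, 1354 higher and 1229 lower, and Serpina3n rose by 2.25.

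**Figure D2:**
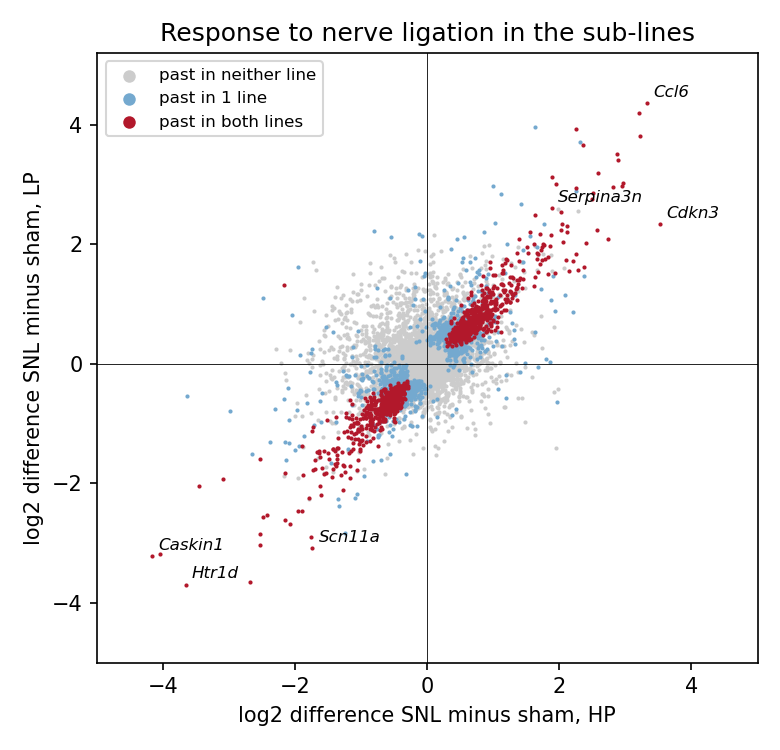
Each point is a gene, with its log2 difference between SNL and sham in HP on the x axis and in LP on the y axis; red genes passed an adjusted p of 0.05 in both lines, blue genes in 1 and grey genes in neither. Genes past in both lines lie at the upper right (528 genes) and lower left (470 genes), with 1 exception.

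Serpina3n, a secreted inhibitor of serine proteases named in the study's title, was measured by 1 probe set. Its signal was 199 ± 38.5 in HP sham, 731 ± 93.5 in HP SNL, 293 ± 77.5 in LP sham and 1760.4 ± 204 in LP SNL. It rose after SNL by log2 1.88 ± 0.20 in HP (limma adjusted p = 0.00039) and by 2.61 ± 0.20 in LP (adjusted p = 7.2e-05), with all 3 SNL arrays above all 3 sham arrays in each line. Arrays of 3 against 3 separate by chance in 10% of cases in either direction. After SNL it was higher in LP than in HP by 1.27 ± 0.20 (adjusted p = 0.0486), and after sham the difference was 0.54 ± 0.20 (adjusted p = 0.429). The response in LP minus that in HP was 0.73 ± 0.28 (unadjusted p = 0.0263, adjusted p = 0.988), so a larger rise in LP did not pass. The line difference after SNL passed in 10 of 24 alternative settings, with adjusted p between 0.0116 and 0.177. With each array left out the difference lay between 1.18 and 1.37, while its adjusted p was 0.0943, 0.0945 and 0.0521 without HP sham replicates 1, 2 and 3, 0.112, 0.127 and 0.0605 without HP SNL replicates 1, 2 and 3, 0.0538 without LP sham replicate 2, and 0.131, 0.177 and 0.1 without LP SNL replicates 1, 2 and 3. Leukocyte elastase, the protease in the title, has the gene symbol Elane, which no probe set carried under a single gene name here.

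**Figure D3:**
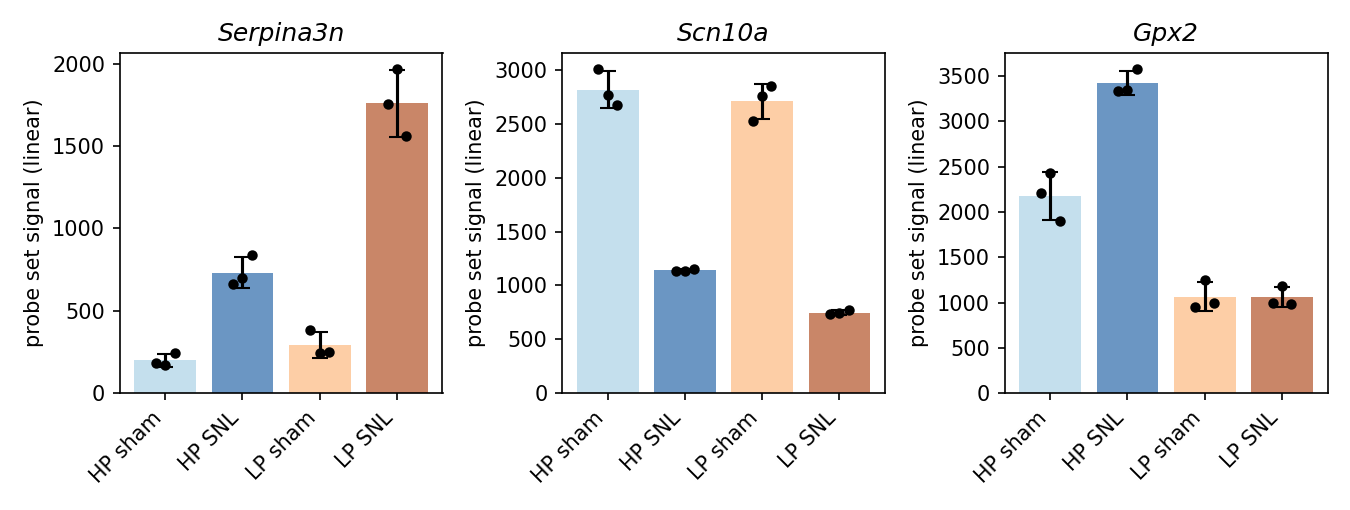
Probe set signals on a linear scale (y axis) of Serpina3n, Scn10a and Gpx2 in the 4 groups; bars are means, error bars SD with n = 3, and points single arrays. Serpina3n is highest in LP SNL (1760.4), Scn10a lowest there (748), and Gpx2 highest in HP SNL (3422).

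Before injury, the lines were compared after sham surgery. Scaf1, a splicing-associated protein, was lower in LP than in HP by -2.10 ± 0.24 (65.0 ± 14.4 against 285 ± 82.1; adjusted p = 0.0495), and was the only gene that limma called of 10411. At an unadjusted p under 0.05 there were 1016 genes, where chance gives 521. Scaf1 lost its call without HP sham replicates 1 and 2 (adjusted p = 0.102 and 0.0953), HP SNL replicates 1 and 2 (0.0765 and 0.0753), LP sham replicates 1, 2 and 3 (0.0732, 0.0744 and 0.106) and LP SNL replicates 1, 2 and 3 (0.104, 0.105 and 0.133), at differences of -2.24 to -1.90. Over all alternatives its adjusted p lay between 0.0101 and 0.389. Without HP sham replicate 3 the count was 2 genes, without HP SNL replicate 3 it was 3, and without each of the other 10 arrays it was 0 by limma. By camera, 4 lists were lower in LP: cytosolic ribosomal proteins (median -0.10, adjusted p = 0.00259), the respiratory chain (-0.09, 0.00259), antigen presentation (-0.16, 0.0246) and macrophage markers (-0.14, 0.0336). Each of the 4 had adjusted p = 0.805 with an estimated correlation, and limma called 0 of their genes over all genes. At an unadjusted p under 0.05, 6, 5, 8 and 8 genes of these lists were lower, and 0, 0, 2 and 2 were higher. Adjusted over the list alone, 5 MHC genes were lower and 2 higher, 3 macrophage genes lower and 1 higher, and none of the others. Among the MHC genes, none of which passed, RT1-Bb had -1.93 ± 0.27, RT1-T24-4 -1.91 ± 0.30 and RT1-CE5 1.21 ± 0.21, with adjusted p of 0.0962, 0.12 and 0.163. The other probe set of RT1-Bb went the opposite way after sham, by 2.07 ± 1.00. Without HP sham replicate 2, the ribosomal, respiratory and macrophage calls were lost (adjusted p = 0.423, 0.418 and 0.173). Without LP sham replicate 1, the ribosomal, antigen presentation and macrophage calls were lost (0.297, 0.267 and 0.267), and the macrophage call also without HP sham replicate 1, HP SNL replicate 3 and LP sham replicate 2 (0.168, 0.0595 and 0.0572). After quantile normalization the ribosomal and respiratory calls were lost as well (0.0855 and 0.069). With the mean of a gene's probe sets the antigen presentation call was lost (median -0.05, camera adjusted p = 0.0855). Skeletal muscle markers did not pass after sham (median -0.11, mean -0.34, adjusted p = 0.0576), but 8 of 32 were lower in LP at an unadjusted p under 0.05, and the list passed in 7 of 25 alternatives (0.000549 to 0.805), among them those without HP sham replicate 2 (0.00284), LP sham replicate 3 (0.0195) and LP SNL replicate 1 (0.0455). The mean log2 signal of the muscle list was 6.98, 6.62 and 6.91 in HP sham replicates 1, 2 and 3 and 6.11, 6.54 and 6.84 in LP sham replicates 1, 2 and 3. Over the alternatives the adjusted p of the ribosomal, respiratory, antigen presentation and macrophage lists ranged from 2.87e-07, 8.6e-06, 0.00376 and 0.00339 to 0.805.

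After ligation, LP and HP differed in 18 genes by limma, 9 higher and 9 lower in LP. Gpx2, a glutathione peroxidase, was lower in LP by -1.70 ± 0.13 (1057 ± 112 against 3422 ± 134; adjusted p = 0.00184). It was already lower in LP after sham, by -1.04, which did not pass over all genes. Its sham signals were 2209, 2428.6 and 1895.3 in HP and 948, 1247.5 and 997.7 in LP. Scn10a was lower in LP by -0.61 ± 0.08 (748 ± 19.4 against 1140.2 ± 11.5; adjusted p = 0.0292), after a sham difference of -0.06 ± 0.08. Sgcb, a sarcoglycan of the membrane complex that anchors dystrophin, and Fam111a, a protease of DNA replication, were higher in LP by 4.33 ± 0.56 and 3.07 ± 0.38. Sgcb was dim in HP SNL, at a signal of 27.7 against 563 in LP SNL. The transcription factor gene Ptf1a and C8h11orf65 were higher by 2.35 ± 0.29 and 2.47 ± 0.34. Both were dim in HP SNL, at signals of 24.8 and 23.7 against 130 and 133 in LP SNL. The 5th percentile of signal per array lay between 12.4 and 20.8. The other probe set of C8h11orf65 gave 0.26 at signals of 0.633 and 1.03, too dim to compare. The MHC class I gene RT1-CE5 was higher by 1.67 ± 0.21, with 4.60 ± 0.87, 1.44 ± 0.29, 0.52 ± 0.28 and 4.04 ± 0.86 for its other probe sets, none of which passed over all probe sets (adjusted p = 0.101, 0.115, 0.544 and 0.141). The probe set that stood for RT1-CE5 and some of the others are of designs that can also read related class I genes. These signals may thus not come from RT1-CE5 alone. Also higher were Tnfrsf14, Pik3r3 and Mfsd5, by 0.95 ± 0.14, 0.81 ± 0.12 and 0.80 ± 0.11. Scaf1 and the MHC class II gene RT1-Bb were lower by -2.09 ± 0.24 and -1.94 ± 0.27, and the other probe set of RT1-Bb gave 3.18. Tmem41a, Fam89a, Aplp1, Myo18a and Cgref1 were lower by between -1.10 ± 0.17 and -0.56 ± 0.09. Of the 18 genes, 16 differed in the same direction after sham, as did 6305 of all 10411 genes. After sham, 14 of the 18 had an unadjusted p under 0.05 by limma, among them C8h11orf65, which went the opposite way (-1.02). Genes are not independent replicates, so no p is given for the count of 16. By limma, 8 of the 18 had an unadjusted interaction p under 0.05, but they were picked by the SNL difference, which enters the interaction. Gpx2 passed in each of 24 alternative settings, with adjusted p up to 0.022. The other 17 lost their calls with some arrays left out, while their log2 differences stayed between 0.84 and 1.18 times those with all arrays. Leaving out a sham array altered none of these differences, only the spread they are tested against. Without HP sham replicates 1, 2 and 3, 6, 1 and 7 of the 18 genes passed, with adjusted p up to 0.0943, 0.0945 and 0.0931. Without HP SNL replicates 1, 2 and 3, 5, 1 and 7 passed (up to 0.113, 0.131 and 0.12). Without LP sham replicates 1, 2 and 3, 12, 14 and 18 passed (up to 0.0636, 0.0666 and 0.0477), and without each of LP SNL replicates 1, 2 and 3 only Gpx2 passed (up to 0.138, 0.177 and 0.157). The count over all genes was 6, 1 and 8 without HP sham replicates 1, 2 and 3, 3 and 10 without HP SNL replicates 2 and 3, and 1, 2 and 2 without LP SNL replicates 1, 2 and 3.

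**Figure D4:**
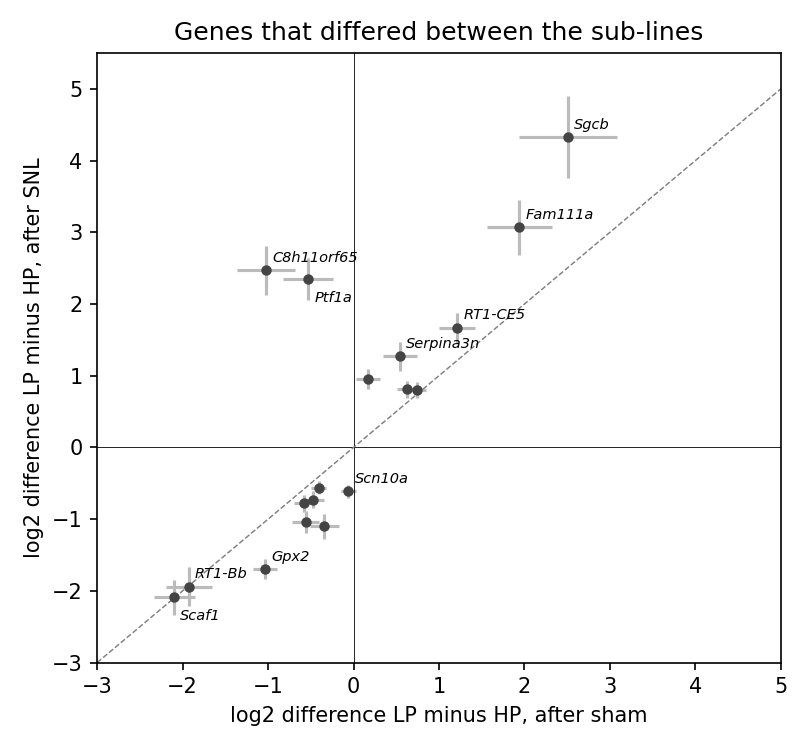
The 18 genes that differed between LP and HP after SNL, with the log2 difference LP minus HP after sham on the x axis and after SNL on the y axis; lines through points are SE and the dashed line marks equal differences. C8h11orf65 and Ptf1a are the 2 genes whose difference changed sign between sham and SNL, and the other 16 lie at the upper right or lower left.

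By camera, 7 lists were lower in LP than in HP after SNL. Nociceptor and sensory neuron markers (median -0.14; 1 of 26 lower over all genes, 6 adjusted over the list alone) had adjusted p = 0.000216, and 0.039 with an estimated correlation. Calca, the precursor of the peptide CGRP, had -0.47 ± 0.09 and Scn11a -1.08 ± 0.21, with adjusted p of 0.0937 and 0.0887. For the other 6 the call was lost: respiratory chain (1.61e-05, but adjusted p = 0.481 with an estimated correlation), neurofilament and cytoskeleton (0.000304, but adjusted p = 0.367), antigen presentation (0.00594, but adjusted p = 0.437), ribosomal proteins (0.00657, but adjusted p = 0.666), synaptic vesicle genes (0.0193, but adjusted p = 0.169) and satellite glia (0.0203, but adjusted p = 0.169, both with an estimated correlation). Over all genes, RT1-Bb was lower and RT1-CE5 higher among the genes of these lists. Adjusted over the list alone, 3 cytoskeleton genes, 10 MHC genes and 3 satellite glia genes were lower, and 1 MHC gene and 1 satellite glia gene higher. Without HP SNL replicate 2, the antigen presentation, synaptic and satellite calls were lost (adjusted p = 0.0528 each). The synaptic and satellite calls were lost without LP SNL replicate 1 (0.0547 each), the ribosomal and satellite calls without HP SNL replicate 3 (0.0676 and 0.0671) and without LP SNL replicate 2 (0.211 and 0.14). After quantile normalization the respiratory, cytoskeleton, synaptic and satellite calls were lost (0.11, 0.425, 0.11 and 0.199) and the ribosomal median turned to 0.01. With the mean of a gene's probe sets the synaptic and satellite calls were lost (camera adjusted p = 0.112 and 0.131). Over the alternatives the adjusted p of the 6 lists reached 0.481, 0.425, 0.437, 0.666, 0.169 and 0.199 in the order given, from 1.9e-06, 5.77e-06, 0.00221, 0.000115, 0.00988 and 0.0059.

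Whether ligation acted differently in the lines was tested by the interaction, the LP response minus the HP response. By limma 0 genes passed an adjusted p of 0.05 (smallest 0.189), and 490 had an unadjusted p under 0.05, where chance gives 521. The genes with the smallest p, none of which passed, included C8h11orf65 (3.48 ± 0.48), Ptf1a (2.88 ± 0.41), Rrs1 (3.59 ± 0.76), the hemoglobin gene Hba-a3 (-0.82 ± 0.16) and Scn10a (-0.55 ± 0.12). C8h11orf65 and Ptf1a were dim in HP SNL (signals of 23.7 and 24.8). Nociceptor and sensory neuron markers had a median interaction of -0.20, a larger fall in LP (camera adjusted p = 0.00051, and 0.0394 with an estimated correlation), in a range of 1e-04 to 0.0394 over the alternatives. By limma 0 of the 26 genes passed over all genes, 3 were lower at an unadjusted p under 0.05, and 2 were lower adjusted over the list alone, Scn10a and Scn11a (-1.34 ± 0.29). Synaptic vesicle genes had -0.14 (adjusted p = 0.00221, and 0.0394 with an estimated correlation; range 0.00049 to 0.0458). Limma called 0 of 30 over all genes and 0 adjusted over the list alone, with 3 lower at an unadjusted p under 0.05, among them Sv2b (-0.49 ± 0.15). Skeletal muscle markers had 0.36 (adjusted p = 0.005, but adjusted p = 0.545 with an estimated correlation; range 3.92e-05 to 0.545), where the mean log2 signal of the muscle list was highest in HP sham replicates 1 and 3 (6.98 and 6.91), nearly as high in replicate 3 of LP sham and of LP SNL (6.84 and 6.82), and lowest in LP sham replicate 1 (6.11). Limma called 0 of these 32 in both adjustments, with 4 higher at an unadjusted p under 0.05. The list's call was lost without HP sham replicate 3 (adjusted p = 0.0758), without LP sham replicate 1 (0.0737), without the dimmest 25% of genes (0.149) and with fry (0.509). Without HP sham replicate 3 and HP SNL replicate 2 the interaction count was 2 genes each, and without HP SNL replicate 3 it was 1.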

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

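Every test of an explanation in this part was chosen after the result was seen, and the gene list tests and the counts over other splits for the averaged response were not. Of the lists tested for a different response in the lines, 3 passed: nociceptor and sensory neuron markers (median interaction -0.20), synaptic vesicle genes (-0.14) and skeletal muscle markers (0.36). Probe sets without a single gene name lay outside the named comparisons, and of 3083 such probe sets 272 passed in HP and 303 in LP after SNL.

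Nociceptor and synaptic vesicle genes fell further in LP, and a different response of the lines, which the design names, remains an open, untested explanation. The synaptic list's mean log2 signal was 9.73, 9.77 and 9.72 in HP sham and 9.78, 9.92 and 9.81 in LP sham. After SNL it was 9.36, 9.38 and 9.4 in HP and 9.23, 9.23 and 9.33 in LP. Part of its larger fall thus lay in the sham arrays, where by limma 4 synaptic genes were higher in LP and 0 lower at an unadjusted p under 0.05. Without Scn10a and Scn11a, camera's adjusted p for the nociceptor list was 0.0115 at the preset correlation. That argues against both genes as the whole pattern at that setting only. With an estimated correlation the full list had 0.0394, and the value of the shorter list is not given here. With the actin ratio as a covariate the full list had 0.00149. This argues against RNA quality as the whole cause only as far as that ratio reads it. Over all 25 alternatives the adjusted p lay between 1e-04 and 0.0394. A lower share of neuronal RNA in LP after SNL cannot be told apart, since the interaction of the 56 nociceptor and synaptic genes exceeded that of 24 cytoskeleton genes by only -0.13 ± 0.07 (-0.22 against -0.09). The cytoskeleton genes are also no fixed gauge of neuronal content, as some of them rose and others fell after SNL in each line. No single gene passed the interaction test, and the shift may also lie in a change of the nociceptor share, which was not tested.

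Another pattern is the difference between LP and HP after SNL in 18 genes. For RT1-Bb, a sequence variant between the lines under the probes is a candidate explanation, because the other probe set differed by 3.18 ± 1.00 against -1.94 ± 0.27, although the former did not pass over all probe sets (adjusted p = 0.323). For the other 17 genes the probe sets cannot tell such a variant from a difference in transcript level. Only 2 of them, RT1-CE5 and C8h11orf65, had another probe set, and no probe sequence was used here. A constant factor from a variant would also appear after sham, in the same direction. By limma 14 of the 18 genes had an unadjusted p under 0.05 there, but 1 of them, C8h11orf65, went the opposite way (-1.02). Scn10a had -0.06 after sham and -0.61 after SNL, which argues against a constant factor for that gene, though its interaction did not pass. Tnfrsf14 and Tmem41a also differed less after sham (0.17 and -0.34) than after SNL (0.95 and -1.10). Scaf1 and Mfsd5 differed nearly equally after sham (-2.10 and 0.74) and after SNL (-2.09 and 0.80). All 18 genes were picked by the SNL difference, so a smaller sham difference alone decides little. C8h11orf65 and Ptf1a changed sign but were dim in HP SNL. The 4 other probe sets of RT1-CE5 were all higher in LP, 3 of them by over 2 SE, but by unequal amounts (0.52 to 4.60) and none past the threshold over all probe sets. The set at 0.52 was dim, with signals of 14.4 in HP SNL and 21.6 in LP SNL. The other probe set of C8h11orf65 gave 0.26 ± 0.76 at signals of 0.633 and 1.03, too dim to speak for or against a variant. A genetic difference in expression between the lines stays open and untested.

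For Serpina3n, higher in LP than in HP after SNL, the difference was 1.35 with the actin covariate and its limma adjusted p 0.0426, where all 24 alternatives gave 0.0116 to 0.177. The actin ratio differed little between these groups (means of 1.23 in HP SNL and 1.12 in LP SNL), which limits what the covariate can show. These values argue against RNA quality as the whole cause only as far as that ratio reads it, and the GAPDH ratio was not tried. A constant factor from a variant under the probe set cannot be told apart: the LP to HP ratio was 1.47 after sham and 2.41 after SNL, but subtracting an unspecific signal of 146 from every group mean makes both 2.76. A regulatory difference between the lines stays open and untested.

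Other splits of the arrays were counted for each comparison. For SNL against sham in HP and in LP, 1 of 10 splits gave as many genes as the real 1419 and 1504, with 1 gene as the highest other in each, and 10 splits are too few for a share under 0.05. The same limit holds for LP against HP after SNL (1 of 10; 18 genes, highest other 1) and after sham (5 of 10; 1 gene, highest other 4). Averaged over the lines, 1 of 100 splits gave as many as 2583 genes, with 2 as the highest other, so other groupings of the arrays within lines do not give such a count. For the interaction the real count was 0, so all 100 of 100 splits gave as many and the test was uninformative, and the highest count of another split was 70 genes, the cause of which was not tested.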

How the results depend on the processing

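Pseudocounts of 16 and 32, the actin covariate and the nociceptor list without Scn10a and Scn11a were chosen after seeing the data, and the other alternatives before. For the named genes with all arrays kept, 7101 results kept their call, passed or not, 180 lost a call, 56 gained one and 1 was reversed. Direction was compared only where the main or the alternative result passed, so a change of sign in a result past in neither counts as kept. With 1 array left out, 7236 kept their call in this sense, 356 lost a call and 28 gained one. The cause was not tested where none is given.

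Counts of genes moved by over 1.5 times as follows. For SNL against sham in HP the count of 1419 was 816 with the actin covariate, and 846 to 1489 with 1 array left out. In LP the count of 1504 was 814 in a fit of only the arrays compared, which has fewer samples. After sham the count of 1 between the lines was 0 with the replicate block, quantile normalization, median centring, only the arrays compared and the mean of probe sets, 2 with pseudocount 32, 3 with the actin covariate, 5 without the dimmest 25%, 6 with trend and robust variance, 7 with every probe set, and 0 to 3 with 1 array left out. After SNL the count of 18 was 4 with only the arrays compared, 9 with the actin covariate, 11 with the mean of probe sets, 29 with pseudocount 32, 34 with array weights, 39 without the dimmest 25% (fewer genes tested), 52 with trend and robust variance, and 1 to 26 with 1 array left out. The interaction count of 0 was 1 with the actin covariate and 0 to 2 with 1 array left out. The correlation of responses, 0.602, was 0.815 without the dimmest 25% and 0.703 with pseudocount 32.

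Serpina3n between the lines after SNL kept its log2 difference of 1.268 but lost its call with the replicate block (adjusted p = 0.153), only the arrays compared (0.122), every probe set (0.0528) and the mean of probe sets (0.057), and ranged from 1.184 to 1.369 with 1 array left out. Lists past the threshold with an estimated correlation numbered 9 in HP, 9 in LP and 10 averaged. After sham the 4 lists became 2 with quantile normalization and with only the arrays compared, 0 with array weights, estimated correlation and fry, and 1 to 6 with 1 array left out. After SNL the 7 became 3 with quantile normalization, 1 with estimated correlation and fry, and 4 to 10 with 1 array left out. For the interaction the 3 became 5 without the dimmest 25% and with quantile normalization, and 2 to 5 with 1 array left out. Among results that passed in the main or the alternative setting, the ribosomal proteins between the lines after SNL were reversed under quantile normalization (median 0.009, adjusted p = 0.544). RT1-Bb there was reversed with the mean of its probe sets (0.623, adjusted p = 0.644), and its probe sets go opposite ways.

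The replicate number as a block gave 1115 genes in HP, 1251 in LP, 2288 averaged and 7 between the lines after SNL. With it Serpinb2 in HP kept its log2 difference of 2.94 and lost its call (adjusted p = 0.0504; range over alternatives 0.00315 to 0.149). The numbers did not pair the arrays: the deviations of 18 same-number pairs correlated between -0.181 and 0.137, with 2 above 0.1, and 4 of 12 arrays correlated best with their own number.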

Other observations

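The list tests in this part were planned, and the signals per array were chosen after the results were seen. After ligation, camera at the preset correlation called ribosomal protein genes higher and respiratory chain genes lower in both lines, and neither call held with an estimated correlation. Of 41 cytosolic ribosomal protein genes, 21 rose in HP (30 adjusted over the list alone) and 19 in LP (31 adjusted over the list alone). In LP the 60S subunit gene Rpl18 rose by 0.60 ± 0.11. Camera gave 3.07e-11 and 6.87e-12, but adjusted p = 0.138 and 0.116 with an estimated correlation. Of 52 respiratory chain genes, 5 fell in each line (4 in HP and 10 in LP adjusted over the list alone), including the complex I subunit Ndufs1 (-0.63 ± 0.11 and -0.71 ± 0.11) and the succinate dehydrogenase subunit Sdha (-0.56 ± 0.12 in HP). Camera gave 4.22e-05 and 1.11e-06, but adjusted p = 0.21 and 0.142 with an estimated correlation.

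Adipocyte markers had 2 risers of 17 in HP and 4 in LP (3 and 4 adjusted over the list alone, with 0 and 2 lower), among them Cidea, a lipid droplet protein (0.70 ± 0.10 and 0.46 ± 0.10), with camera adjusted p of 0.181 and 0.213. Central nervous system glia markers had 3 risers and 2 fallers of 15 in HP and 3 and 3 in LP (3 and 3 in each adjusted over the list alone), with the metallothionein Mt3 at -0.87 ± 0.12 and -0.74 ± 0.12 and camera adjusted p of 0.957 and 0.961. Of these 15 markers 10 belong to another list too. In LP their median and mean lay above 0 and the test below. Of 8 red blood cell markers, 2 rose in HP (3 adjusted over the list alone) and 0 in LP by limma (0 adjusted over the list alone and 0 at an unadjusted p under 0.05), with camera adjusted p of 0.234 and 0.961 and, in LP, a median of 0.00 with the test below 0. Hba-a3 rose in HP by 0.67 ± 0.11, with signals of 1919.4, 1817.8 and 1649.1 after sham and 2487, 2961.9 and 3176.6 after SNL, and had -0.15 ± 0.11 in LP. The Hba-a3 interaction of -0.82 ± 0.16 did not pass (adjusted p = 0.682).

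Of the 32 skeletal muscle markers, 4 lay above the median gene level and 2 belong to another list. Myh4, a fast myosin, had signals of 123.7, 38.7 and 154.1 in HP sham replicates 1, 2 and 3, 3.8, 9.3 and 7.0 in HP SNL, 3.1, 17.5 and 61.0 in LP sham, and 4.9, 6.3 and 34.0 in LP SNL. Myl1, a myosin light chain, had 345.9, 144.3 and 380.1 in HP sham and between 95.3 and 168.7 on the other 9 arrays.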
